A study of Schizosaccharomyces pombe with 3 samples.

How the data were processed

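Chromatin bound by the corepressor subunit Tup11, tagged with green fluorescent protein (GFP), was immunoprecipitated with an antibody against GFP from fission yeast (Schizosaccharomyces pombe) grown to mid-log phase in rich YES medium. Per the labels' protocols, precipitated and input DNA came from separate experiments, were amplified in a first and a second round, labelled with Cy5 and Cy3, and hybridised together on spotted arrays that carry PCR products of open reading frames (ORF features) and of intergenic regions (intergenic features). There were 3 two-colour arrays, all of one group: replicates 1 and 2 from print batch E120D and replicate 3 from print batch F060D. No array of an untagged strain or of another condition was analysed here, so every ratio is precipitate over input within one strain and one medium.

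The deposited scanner tables hold spot intensity on a linear scale for a channel A and a channel B, as the integrated signal after subtraction of the local background by TIGR Spotfinder, per the file headers and the labels' protocols. Rejected spots are listed at 0 in these tables. The deposited value tables appear to hold log10 values of a single channel, scaled to the array's median, with -2 for a missing value. This reading comes from comparison with the scanner tables, under the exchange of names described below. The match was close on replicate 3 (r = 0.97 with channel A) and loose on replicates 1 and 2 (r = 0.64 and 0.47 with channel B). Both channels together reached r = 0.647 and 0.515 on replicates 1 and 2, so what their value tables hold is not settled. Per the labels' protocols the authors scaled to the 50th percentile in GeneSpring, removed flagged values, ranked ratios by median percentile and set the binding list at the 85th percentile. In the value tables the medians of the rows that hold a value were 0.04, 0.14 and 0.01 for replicates 1 to 3. Over all rows the medians were -0.05, -0.21 and -0.08, and 6310, 10058 and 3822 rows held no value. Why these tables would hold one channel and not a ratio stays unknown, and they are called values of a single channel below. Software versions and the genome build behind the feature names are not given in the sources used here.

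The scanner files do not say which letter is which dye. As channel B over channel A, replicate 3 correlated with replicate 1 at r = -0.54 over 7718 features and with replicate 2 at r = -0.40 over 4344 features, while replicates 1 and 2 correlated at r = 0.73 over 4237 features. The arrays therefore have no direction settled by the labels. The precipitate was taken as the channel that the value table follows. ORF and intergenic names were exchanged between the tables for a regression on both channels. The slope of the channel followed was 1.10 for B on replicate 1, 0.86 for B on replicate 2 and 1.09 for A on replicate 3. The fits had r = 0.647, 0.515 and 0.971. With each row's own name these slopes were 0.484, 0.061 and 0.529, and channel A of replicate 2 had 0.036, close to its channel B. The direction taken is likely and not certain. Under it the 6 measured mitochondrial features, which a chromatin protein of the nucleus does not meet, were low on every array, with medians of -3.10, -3.77 and -2.12. The comparisons, and the later tests of words, windows and explanations, are also given with replicate 3 read with the same channel letters as the other arrays. Turning the sign of an array that correlates with the others shrinks what they share by construction. Calls lost in that reading show how far a result rests on the direction of replicate 3, and do not test the result. Most single features named as list members are given in the likely direction only, and reading all arrays the other way round would turn every sign.

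The value tables carry feature names in which ORF and intergenic features are exchanged relative to the scanner tables. Names were taken from the scanner tables, because their 64 Ef1-b control spots had centred log2 ratios of -0.56, -0.79 and 0.71 on replicates 1 to 3, close to the ORF feature ef1-b at -0.57, -0.98 and 0.52 and far from the intergenic feature of ef1-b at 3.30, 1.69 and 3.61. Features were matched by gene name to the reference genome ASM294v3, and 95.2% of them received coordinates. ORF features carry the coordinates of the coding sequence. Intergenic features carry those of the whole gap between neighbouring coding sequences or RNA genes, since the ends of the PCR products were not used here, so 2 features of one gap share coordinates. An intergenic feature was placed 5' of the gene it is named for: on replicate 3 its ratio correlated across features with the ORF of the upstream neighbour (Spearman rho = 0.33) and of its own gene (0.34) more than with the downstream neighbour (0.14), and the 1050 pairs named for both genes of a divergent gap correlated at 0.51, against 0.20 for intergenic features of other adjacent genes. ORF features of divergent genes correlated at 0.26 and those of other adjacent genes at 0.23, whereas with exchanged names the ORF features would be those that share a gap. This check of the names was added after seeing the data. The labels do not state which naming is right, and the other one would exchange intergenic and ORF features in every result. Features are not independent replicates in these correlations.

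Spots flagged as rejected or saturated in either channel, control spots, and spots named as missing products were left out. This kept 71.5%, 36.4% and 99.2% of 19976 yeast spots on replicates 1 to 3, or 7730, 4352 and 9919 features. The median signal over local background was 2.86, 2.47 and 17.4 for the precipitate and 6.40, 6.02 and 14.3 for the input. On replicates 1 and 2, 3635 and 6935 spots had a precipitate signal but no detected input, against 2 spots on replicate 3, so features with a weak input spot are missing more often. The log2 ratio of precipitate over input was centred on each array's median with no loess, and repeat spots were averaged. The tests used the 4230 features measured on all 3 arrays (1535 intergenic, 2692 ORF, the rest intronic). The number of arrays limits the precision.

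The binding list held features whose median percentile rank over all spot values of the 3 arrays reached 85, set against 1000 shuffles of feature names within each array. Features were tested against the array median with limma 3.58.1 (intercept fit, eBayes, two-sided, Benjamini-Hochberg at 0.05) in R 4.3.3. The fit gave every feature the same standard error of 0.342, so a call depended on the mean alone, and the smallest absolute mean called was 0.87. Differences between kinds of feature were taken as differences of medians per array with an exact sign-flip test, two-sided, whose smallest p with 3 arrays is 0.25, and as Fisher's exact test of list membership over features, which treats neighbouring features as independent. Gene lists were tested with camera at a preset correlation of 0.01, for upstream intergenic and ORF features apart, with Benjamini-Hochberg over 36 tests. An intergenic feature counted for the gene it is named for and for the other gene of a divergent gap. The lists held genes of the corepressor subunits, glucose repression, hexose transport, iron uptake, copper and zinc, phosphate and thiamine, stress response, cation transport, mating and meiosis, amino acid and nitrogen permeases, flocculins, transcription factors, MBF cell cycle control, glycolysis, ribosomal proteins, translation factors, histones, the proteasome and the respiratory chain. The list names are broad. The iron uptake list also holds the phytochelatin transporter gene hmt1, the hexose transporter list the gluconate symporter gene ght3, and the glucose-repressed list the repressor gene scr1. No measured feature matched the list of retrotransposons, and the corepressor subunits had 2 measured ORF features and no measured intergenic feature, under the 3 needed for a test.

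Named features were the 15 intergenic and 10 ORF features with the highest mean on the list and at rank 85 or more on every array, the 5 lowest of each kind under rank 15 on every array, the features of 14 fixed genes, and up to 4 of the highest members per list and kind. The tests were also run on simulated data with the real spreads. Of 200 features shifted by 2 on the log2 scale among 4230, limma recovered 68.5% with 4.2% false calls, and of those shifted by 3 it recovered 89.5%. Of those shifted by 1 it recovered 0%, whereas the main fit called means from 0.87. The simulated fit thus behaved unlike the main one, and its rates of recovery and false calls do not describe the main calls. Camera called a list of 75 members shifted by 0.5 and no other of the 36 tests. The simulated features were drawn independently, so this could not test whether the preset correlation suits the real features. With independent simulated arrays, 260 features reached the list against a shuffled mean of 255.2. The lists, tests, named-feature rule and most other settings tried were fixed before the data were examined. Those settings were normexp background correction, loess, centring intergenic and ORF features apart, keeping saturated spots (any spot with a signal above 0 in both channels, while rejected spots stayed at 0), leaving out dim input spots, the deposited values, leaving out each replicate, removing GC content and length by lowess, features on at least 2 arrays, other percentiles and distances, and other forms of limma and camera. The planned comparison of promoter-containing with convergent gaps could not be made. Placing every intergenic feature 5' of its gene leaves none in a convergent gap, whatever the array carries. Divergent was compared with tandem gaps in its place. That comparison, the reading of replicate 3 with the same letters, centring on the shared features, setting an undetected input to a low signal, and chromosome-end features by kind were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used for the rest.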

Results

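Genome-wide occupancy of Tup11 was measured by hybridising immunoprecipitated and input chromatin to arrays of intergenic and ORF features. Tup11 is the fission yeast counterpart of the budding yeast corepressor Tup1 and acts with Tup12 and Ssn6. There was a single group of 3 arrays, replicates 1 to 3, from separate experiments per the labels' protocols. The comparisons below ask where precipitate exceeded input, on which kind of feature, and near which genes. Values are log2 of precipitate over input, centred on each array's median, as mean ± SD (n = 3), and an upstream region is the intergenic feature 5' of the named gene. Of 4230 features, 485 lay above the array median and 418 below it (limma adjusted p under 0.05). The count below was 30 without replicate 1, 109 without replicate 2, 696 without replicate 3, 120 with loess and 0 when limma's prior followed a trend (499 at an unadjusted p under 0.05), and the count above was 228 without replicate 1. The p-values set each mean against a standard error shared by all features, from spread between these 3 arrays of amplified material. They do not measure a feature's own spread, which the SD gives. The direction of replicate 3 rests on its deposited values and not on a stated dye, and with the same channel letters as the other arrays no feature passed, with 126 at an unadjusted p under 0.05.

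The 15 intergenic features with the highest ratios include regions upstream of genes of glycolysis, iron uptake and salt stress, beside others of varied function. The region upstream of pgk1, which encodes phosphoglycerate kinase of glycolysis, had the highest mean in the likely direction at 3.36 ± 0.94 (chromosome II, 4159417 to 4161555, adjusted p = 2.43e-19 in limma). Its gap is bounded on the other side by the rRNA gene SPRRNA.37, and how near the PCR product lies to that gene is not known here. The gap shared by fio1 and fip1, a ferroxidase and a permease of reductive iron uptake, reached 3.11 ± 0.84 for the fio1 feature and 3.02 ± 0.96 for the fip1 feature (chromosome I, 4234497 to 4235638), while a further feature of this gap, also named for fio1, had 1.08 ± 0.24. The gap between shu1, a haem uptake gene, and str3, a siderophore or haem transporter gene, reached 3.07 ± 0.52 (chromosome I, 86279 to 88366). The region upstream of cta3, which encodes a cation-transporting ATPase induced by salt stress, reached 2.66 ± 0.44 (chromosome II, 604921 to 608170).

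The other features among the 15 highest intergenic ones lay upstream of SPAC1002.20 at 3.33 ± 0.51 (chromosome I, 1823190 to 1823971, the gap shared with psu1), gto1 at 3.30 ± 0.83 (chromosome I, 5474549 to 5476876) and mug24 at 3.00 ± 1.13 (chromosome III, 1917543 to 1919281, shared with hmt1). The features of ef1-b at 2.94 ± 0.97, without coordinates here, of SPAC323.07c at 2.91 ± 0.33 and of SPBC887.17 at 2.88 ± 0.78 followed. Both of the last named genes encode predicted transporters. The gap of thf1 and tef103, the latter an elongation factor gene, reached 2.81 ± 0.96, and that of the galactose genes gal10 and gal1 reached 2.75 ± 0.50 (chromosome II, 4487419 to 4488490). The nicotinic acid transporter gene tna1 had 2.75 ± 0.80 upstream, and psk1 had 2.69 ± 0.53. All 15 passed the limma test, with adjusted p of 1.42e-12 or lower. With replicate 3 read with the same letters their means remained above 0, between 0.33 for mug24 and 0.93 for pgk1, and none passed. Both outcomes largely follow from the change of sign, since replicates 1 and 2 keep their high values. The order depends on the direction of replicate 3: in the same-letters reading the gap of zip1, with 1.73 ± 1.48 in the likely direction, had 1.31 and the gap of scr1 0.94, both above pgk1.

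**Figure D1:**
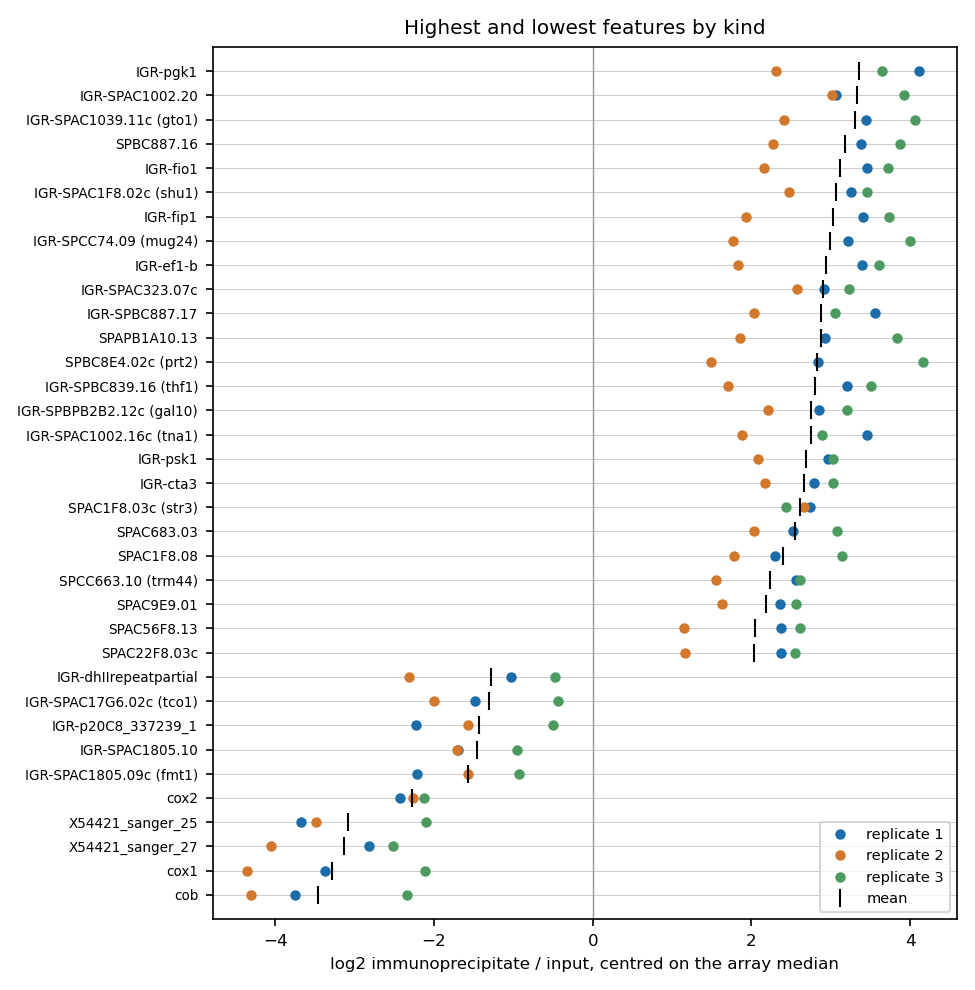
Log2 precipitate over input, centred on the array median (horizontal axis), for the 15 highest intergenic, 10 highest ORF and 5 lowest features of each kind, with a coloured point for each of the 3 replicates and a black mark for the mean. Names starting with IGR are intergenic features, with the reference gene in brackets where it differs. The features with the highest means reach 3.36, and the mitochondrial features cob and cox1 lie at -3.47 and -3.29.

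Among the highest ORF features several had short coding sequences or lay beside a raised upstream region. SPBC887.16, next to the raised gap of SPBC887.17, had 3.18 ± 0.81 over a coding sequence of 330 bp. SPAPB1A10.13 had 2.87 ± 0.99, the feature matched to prt2, a non-coding RNA gene, 2.83 ± 1.34, and str3 2.62 ± 0.16. SPAC683.03 (318 bp) had 2.55 ± 0.53, SPAC1F8.08 (363 bp) 2.40 ± 0.69 and trm44 (1509 bp) 2.24 ± 0.60. SPAC9E9.01 had 2.18 ± 0.49, SPAC56F8.13 2.05 ± 0.78 and SPAC22F8.03c 2.03 ± 0.76. In the same-letters reading of replicate 3 these 10 means lay between 0.05 for prt2 and 0.99 for str3, with 0.31 for SPAPB1A10.13 and 0.60 for SPBC887.16, and none passed. The lowest ORF features were mitochondrial, with cob at -3.47 ± 1.01, cox1 at -3.29 ± 1.13 and cox2 at -2.27 ± 0.15. Features X54421_sanger_27 at -3.13 ± 0.81 and X54421_sanger_25 at -3.09 ± 0.86 also counted among the 6 mitochondrial features. The lowest intergenic features were those of fmt1 at -1.57 ± 0.64, SPAC1805.10 at -1.45 ± 0.43, p20C8_337239_1 at -1.44 ± 0.87 and tco1 at -1.31 ± 0.79, and a centromeric dh repeat of chromosome II at -1.28 ± 0.94, whose copies are near-identical and whose value is therefore uncertain. The features of fmt1 and SPAC1805.10 belong to the same divergent gap and are not separate regions. That gap is shorter than 50 bp in the reference and has no coordinates here, so these products may hold coding sequence. In the same-letters reading cob had -1.90, cox1 -1.88, cox2 -0.86, fmt1 -0.95 and SPAC1805.10 -0.82.

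For genes fixed before the data were examined, the upstream feature was often above the median where the ORF was not. The feature named for wwm3, in the gap of 199143 to 202535 on chromosome II that it shares with the gluconeogenic gene fbp1, had 2.57 ± 0.39, while a further feature of the same gap named for fbp1 had -0.25 ± 0.75 (adjusted p = 0.644 in limma) and the fbp1 ORF 0.04 ± 0.41. Upstream of frp1, a ferric reductase gene, the ratio was 2.53 ± 0.33, and over its ORF 0.89 ± 0.25. Upstream of the siderophore transporter gene str1 it was 1.51 ± 0.43 against 0.29 ± 0.40 over the ORF, and upstream of the acid phosphatase gene pho1 1.49 ± 0.40 against -0.45 ± 0.86. The cta3 ORF had 0.45 ± 0.49. The upstream feature of the thiamine-repressed gene nmt1 had -0.51 ± 0.16 and did not pass. The same-letters values, upstream and over the ORF, were 0.66 and 0.24 for frp1, 0.64 and 0.12 for cta3, 0.20 and -0.73 for pho1, and 0.56 for the wwm3 feature against 0.11 for the fbp1 ORF. For str1 the order turned, with 0.25 upstream and 0.37 over the ORF. The ORFs of inv1 (0.26 ± 0.55), ste11 (0.16 ± 1.49) and act1 (-0.12 ± 0.32) did not pass, and that of adh1, alcohol dehydrogenase, did at 0.89 ± 0.77. The ORFs of the corepressor's own genes tup11 and ssn6 had -0.75 ± 0.91 and -0.87 ± 0.93, neither passing (-0.95 and -0.92 with the same letters), and their upstream features were not measured on all arrays. No feature on the array was matched to tup12.

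The binding list, built by the rank rule of the protocol, held 445 of the 4230 features, of which 378 were intergenic and 67 were ORF features. Genes with a listed upstream region included pgk1, fio1, shu1, cta3, frp1, str1, pho1 and scr1, the glucose repressor gene. In 1000 shuffles of feature names within each array the list held 237.6 ± 11.4 features (mean and SD over shuffles) and at most 273, which gives the smallest p that the shuffles can give, 0.001. Shuffled within intergenic and ORF features apart, it held 352.2 ± 11.2 and at most 387. Of the 445 features, 224 reached the 85th percentile on every array, among them 201 intergenic ones. Under the same-letters reading of replicate 3 the list held 277 features, of which 217 were on the first list, and 75.8% of it was intergenic in place of 84.9%.

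Intergenic features lay above ORF features on every array. The medians of intergenic features were 0.25, 0.60 and 0.30 on replicates 1 to 3, and those of ORF features -0.69, -0.17 and -0.11. The difference was 0.71 ± 0.27 (n = 3, exact sign-flip p = 0.25, the smallest that 3 arrays allow). It fell to 0.204 with GC content and length removed and to 0.191 in the deposited values of a single channel, and rose to 1.18 with normexp. On the binding list were 24.6% of intergenic features, such as those of gto1 and psk1, and 2.49% of ORF features, such as str3 and fip1 (Fisher's exact test over features, odds ratio 12.8, p = 2.16e-111). The shares were 13.7% and 2.5% with the same letters for replicate 3, 19.1% and 5.6% with GC content and length removed, 16.3% and 8.1% in the deposited values, and 12.7% and 3.6% with undetected input set to a low signal. Of intergenic features 407 were above and 23 below the array median in limma, and of ORF features 78 were above and 394 below. Centring on the shared features in place of the whole array gave 607 features above and 248 below, which is 71.0% above among calls against 53.7%. With replicate 3 read with the same letters its difference was -0.41 and the mean 0.44 ± 0.74. Print batch E120D (2 arrays) gave 0.86 and F060D (1 array) 0.41.

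**Figure D2:**
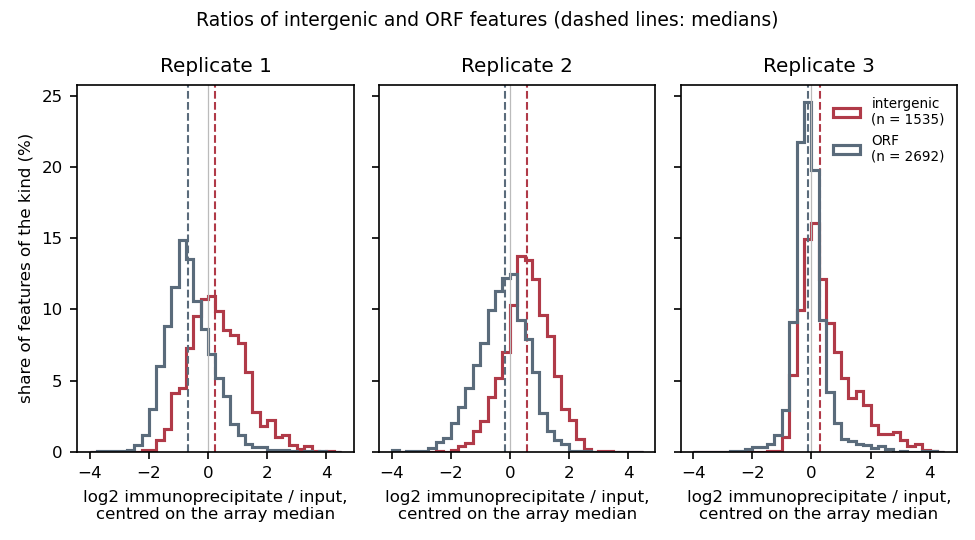
Distribution of centred log2 ratios (horizontal axis) of 1535 intergenic and 2692 ORF features on each of the 3 replicates, as the share of features of each kind in percent (vertical axis), with dashed lines at the medians. The intergenic median lies to the right on each array, at 0.25, 0.60 and 0.30 against -0.69, -0.17 and -0.11.

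Gaps between divergent genes, such as that of fio1 and fip1, and gaps between tandem genes differed little in ratio. The difference of medians was -0.02 ± 0.02 (n = 3, exact sign-flip p = 0.50, where 0.25 is the smallest possible), and -0.03 ± 0.02 with replicate 3 read with the same letters. On the binding list were 26.5% of 845 divergent and 21.0% of 591 tandem features (Fisher's exact test, odds ratio 1.36, p = 0.017). This call was lost with any single replicate left out: the odds ratio was 1.17 without replicate 1, 1.24 without replicate 2 and 0.988, on the other side of 1, without replicate 3.

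Raised upstream regions were frequent among iron uptake genes. Of 20 measured features upstream of iron uptake genes, 15 were above the array median and 0 below, with a list median of 1.59 against 0.39 for all intergenic features (camera adjusted p = 2.23e-08, and adjusted p = 0.949 with an estimated correlation). The called lists all share this value of 0.949 after adjustment, and the unadjusted camera p here was 0.065. The highest members were fio1, shu1, fip1 and the gap of the vacuolar phytochelatin transporter gene hmt1 (3.00 ± 1.13). Features of one gap, such as those of fio1 and fip1, counted as separate members here and in the lists below. The members are therefore not all separate regions. Adjusted over the list alone, 15 were above. Of 12 ORF features of the list, 4 were above and 0 below (camera adjusted p = 3.04e-05, and adjusted p = 0.949 with an estimated correlation), namely str3 at 2.62 ± 0.16, fip1 at 1.94 ± 0.23, shu1 at 1.53 ± 0.31 and frp1 at 0.89 ± 0.25, and 4 adjusted over the list alone.

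Of 16 features upstream of glycolysis genes, 13 were above and 0 below, and 14 were above adjusted over the list alone, with a median of 1.77 (camera adjusted p = 2.23e-08, and adjusted p = 0.949 with an estimated correlation). The gap of pdc101, pyruvate decarboxylase, reached 2.61 ± 0.84, and a further feature of this gap, counted apart, 2.34 ± 0.91. The region upstream of gpd3, glyceraldehyde-3-phosphate dehydrogenase, reached 2.35 ± 0.90. Of 6 ORF features of this list, 1, adh1, was above and 0 below (camera adjusted p = 0.0661). Glucose-repressed genes had 8 of 16 upstream features above and 0 below, and 8 above adjusted over the list alone, with a median of 1.10 (camera adjusted p = 0.00433, and adjusted p = 0.949 with an estimated correlation). Besides the gap of fbp1 these were led by dak2, dihydroxyacetone kinase, at 2.49 ± 0.11 (chromosome I, 66680 to 67142), the gap of scr1 and clg1 at 2.43 ± 0.22 (chromosome II, 1747427 to 1753588) and the transporter gene ght3 at 2.07 ± 0.47. Of 13 ORF features of glucose-repressed genes 2 were above, ght3 at 1.40 ± 0.41 and dak2 at 1.01 ± 0.50, and 0 below (camera adjusted p = 0.014, and adjusted p = 0.949 with an estimated correlation). Of 7 features upstream of hexose transporter genes 5 were above and 0 below, 5 above adjusted over the list alone, with a median of 1.40 (camera adjusted p = 0.0166, and adjusted p = 0.949 with an estimated correlation), among them both features of the ght6 gap at 1.93 ± 0.42 and 1.86 ± 0.33. The hexose transporter and glucose-repressed lists share members such as ght3 and ght6.

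Of 22 features upstream of stress response genes 12 were above and 0 below, 13 above adjusted over the list alone, with a median of 1.25 (camera adjusted p = 0.0076, and adjusted p = 0.949 with an estimated correlation). They were led by cta3, by gpd1, the osmotic stress glycerol-3-phosphate dehydrogenase gene, at 2.49 ± 0.38 (chromosome II, 4031817 to 4035813), and by the features of the ssa1 gap, a heat shock protein gene, at 2.28 ± 1.23 and 2.16 ± 0.70. The gpd1 gap is bounded on its other side by the tRNA gene SPBTRNAASN.03. The camera adjusted p was 0.644 or more in each of the 36 tests, those below included, with replicate 3 read with the same letters. Without replicate 3 the stress response list (camera adjusted p = 0.138) and the ORF features of glucose-repressed genes (0.0684) lost their calls. The mean difference from all features of the kind was then 0.41 for the former, against 0.58 with all arrays. For the latter it did not fall, at 0.55 against 0.53. In the same-letters reading, where the median of all intergenic features was 0.14, the medians were 0.44 for iron uptake, 0.20 for glycolysis, 0.20 for glucose-repressed, 0.44 for hexose transporter and 0.06 for stress response upstream features.

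**Figure D3:**
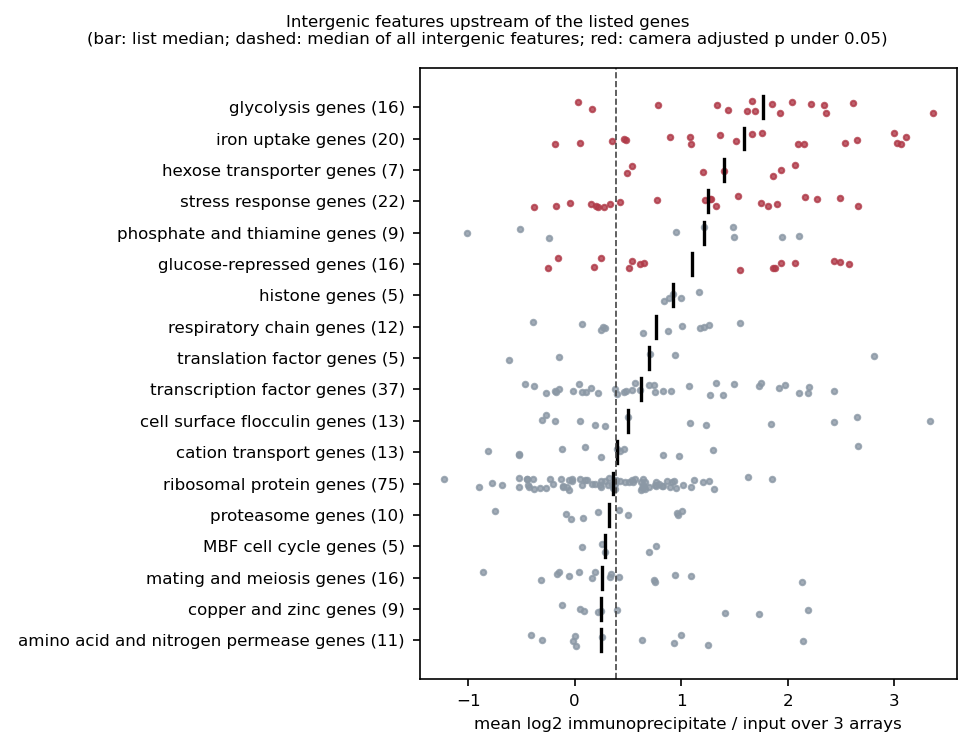
Mean log2 precipitate over input on 3 arrays (horizontal axis) of each measured intergenic feature upstream of the listed genes, with the number measured in brackets. A black bar marks each list's median, the dashed line the median of all intergenic features at 0.39, and red the 5 lists with a camera adjusted p under 0.05. The glycolysis and iron uptake medians lie at 1.77 and 1.59, and that of ribosomal protein genes at 0.36.

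The remaining lists did not pass, and many of their features were not measured. Upstream features measured on all 3 arrays ranged from 5 of 19 on the array for MBF to 13 of 23 for cation transport genes. For the called lists they were 20 of 23 for iron uptake, 16 of 20 for glycolysis and 7 of 11 for hexose transporter genes. For glucose-repressed genes they were 16 of 30 and for stress response genes 22 of 45. Called and uncalled lists were thus unequally covered. Of 75 features upstream of ribosomal protein genes 12 were above and 2 below, with a median of 0.36 (camera adjusted p = 0.355), the highest being rpl2501 at 1.85 ± 0.12. Of 37 features upstream of transcription factor genes 14 were above and 0 below (camera adjusted p = 0.103), with the gap of scr1, rsv2 at 2.20 ± 0.71, the gap of loz1 and SPAC683.03 at 2.19 ± 0.98 and the gap of pho7 and cbp4 at 2.11 ± 0.26 at the top. The feature of that gap named for loz1 itself had 0.40 ± 0.42 and did not pass. Flocculin and cell wall genes had 6 of 13 above (camera adjusted p = 0.0827), led by the gap of psu1, a wall protein gene, and by the gap of pfl7 and abc3 at 2.65 ± 0.48. Phosphate and thiamine genes had 6 of 9 above and 1 below (0.418), among them pho842 at 1.94 ± 0.68. Respiratory chain genes had 6 of 12 above (0.671), led by cyc1 at 1.55 ± 0.42, and histone genes 4 of 5 (0.408), led by hhf2 at 1.17 ± 0.49. Amino acid and nitrogen permease genes had 4 of 11 above (0.958), led by isp5 at 2.14 ± 0.50, and cation transport genes 3 of 13 (0.876). Copper and zinc genes had 3 of 9 above (0.68), mating and meiosis genes 3 of 16 (0.695), led by map2 at 2.13 ± 0.77, and proteasome genes 3 of 10 (0.705). Translation factor genes had 2 of 5 above (0.68), and MBF cell cycle genes 0 of 5 (0.883). Among ORF features, hexose transporter (camera adjusted p = 0.0577), stress response (0.0661), histone (0.103) and cation transport genes (0.427) also did not pass. The same held for translation factor (0.418), mating and meiosis (0.511), flocculin (0.571), respiratory chain (0.68), proteasome (0.68), transcription factor (0.706), ribosomal protein (0.708), permease (0.846), MBF (0.883), copper and zinc (0.883) and phosphate and thiamine genes (0.929).

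Features within 100 kb of an end of chromosome I or II lay above the rest of these chromosomes. They include the upstream regions of shu1, dak2, ght3 and gal10 and the str3 ORF. The difference of medians was 0.69, 0.45 and 0.59 on replicates 1 to 3, a mean of 0.57 ± 0.12 (n = 3, exact sign-flip p = 0.25, the smallest that 3 arrays allow). On the binding list were 29.1% of 110 such features against 9.21% elsewhere (Fisher's exact test, odds ratio 4.05, p = 6.54e-09). These shares were 17.3% and 6.2% with the same letters, 15.9% and 7.7% with undetected input set to a low signal, and 12.3% and 4.4% without dim input spots. They were higher in the deposited values, at 50.7% and 10.2%, and after loess, at 35.5% and 11.6%. The difference of medians was smaller within each kind, at 0.269 for intergenic and 0.437 for ORF features. Over both kinds it was 0.278 with GC content and length removed and 0.325 with the kinds centred apart. With normexp it was 0.961 and in the deposited values 1.02. For ORF features alone the shares were 19.6% and 1.76% (Fisher's exact test, odds ratio 13.6, p = 1.42e-08) and for intergenic features 38.9% and 23.7% (Fisher's exact test, odds ratio 2.05, p = 0.0147). Within 50 kb the difference of medians was 0.16, and with replicate 3 read with the same letters the mean was 0.18 ± 0.68.

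**Figure D4:**
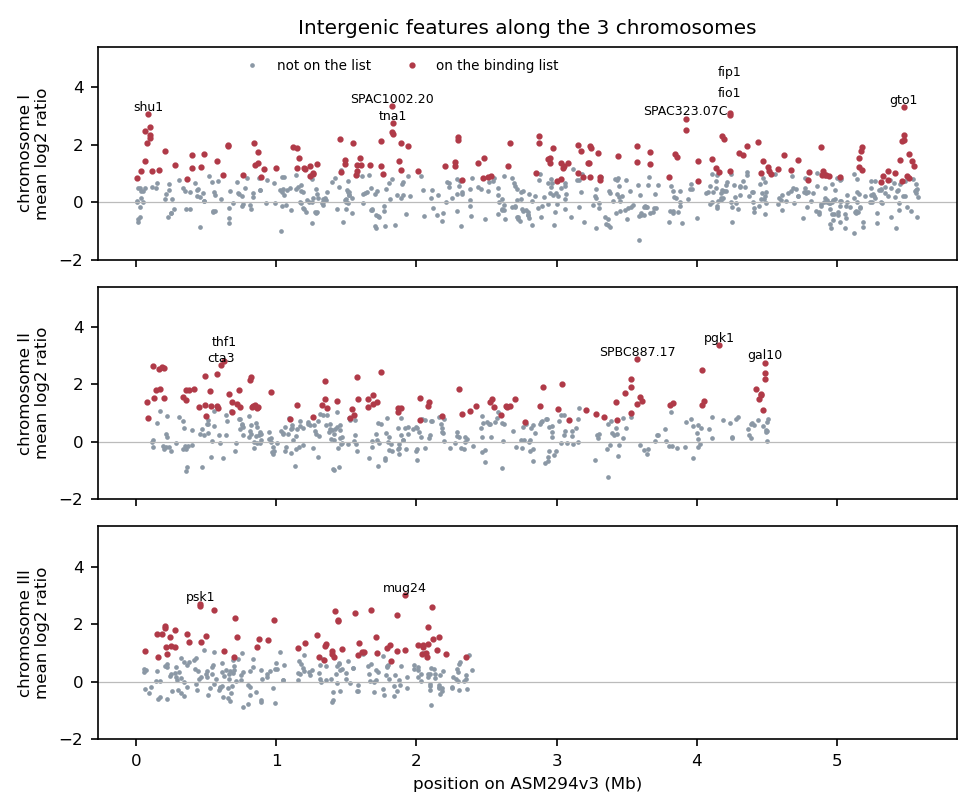
Mean log2 precipitate over input on 3 arrays (vertical axis) of intergenic features at the middle of their gap on chromosomes I, II and III of ASM294v3 (horizontal axis, Mb), with features on the binding list in red. Gene names mark those of the 15 highest intergenic features that have coordinates, such as pgk1 at 3.36 and gto1 at 3.30.

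Agreement between arrays differed by pair and by kind of feature. Across the 4230 features, which are not independent replicates, Pearson's r was 0.73 for replicates 1 and 2 (Spearman's rho 0.73), 0.68 for 1 and 3 (0.53) and 0.41 for 2 and 3 (0.34). For intergenic features r was 0.69, 0.77 and 0.43, and for ORF features 0.66, 0.47 and 0.21. Repeat spots of a feature on one array correlated at 0.94, 0.91 and 0.97. With the same letters, r between replicates 1 and 3 was -0.68 and between 2 and 3 -0.41.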

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

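Spots of 2 sequences from outside the yeast genome, which no comparison above uses, gave input signals above the level of the array's negative controls on every array. That level is the 99th percentile of 320 spots of buffer, luciferase and bacterial sequences, and it was 0, 87478 and 712835 on replicates 1 to 3. The Gfp spots, which hold the sequence of the tag, had median input signals of 816159.5, 553044.5 and 1851470 on replicates 1 to 3. The KanMX spots, which hold a selection marker used in strain building, had 207841, 128458 and 926924.5. Their centred log2 ratios were -0.81, -1.47 and 0.27 for Gfp and 0.43, -0.30 and 0.76 for KanMX. Each sequence had 2 spots per array. With 3 arrays in a single group, no test for a single deviating array and no comparison of effects between groups applied.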

How the results depend on the processing

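The reading of replicate 3 with the same letters, centring on the shared features, the setting of an undetected input to a low signal, the comparison of divergent with tandem gaps and the chromosome-end features by kind were chosen after seeing the data. Where no cause is named below, the cause was not tested.

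With replicate 3 read with the same letters the binding list held 277 features, the intergenic minus ORF difference was 0.435, the divergent against tandem odds ratio 1.13, the chromosome-end difference 0.18 and the mean r between arrays -0.12, since turning the sign of an array turns its correlations. Limma then called 0 features above and 0 below (126 at an unadjusted p under 0.05), and camera 0 lists. Such losses follow by construction when the sign of a correlated array is turned. The mean difference of the glucose-repressed list was 0.07 and that of the stress response list -0.04 (upstream features), with camera's direction down for both.

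The deposited values of a single channel gave 816 listed features, 0.191 for intergenic minus ORF, 1.02 for chromosome ends, a mean r of 0.345, 17 lists, and 0 features above and 0 below in limma (974 at an unadjusted p under 0.05). With them the upstream feature of SPAC1805.10 had 0.22 and that of tco1 1.24, above the median and not below it. Values of a single channel are not divided by input. If the tables hold such values, they are another measure than the ratio, and the differences do not show that enrichment changes. Without dim input spots 150 features were listed among 2908, chromosome ends differed by 0.413 and 161 features lay above. With undetected input set to a low signal the divergent against tandem odds ratio was 1.09, the chromosome-end difference 0.289, the mean r 0.347, with 101 features above, 201 below and 2 lists called. The binding list then held 650 of 8199 features, among them only 130 of the 445 main ones. With features on at least 2 arrays the list held 884 among 7839 features. At the 95th percentile it held 165 and on every array 224, fewer by construction.

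Removing GC content and length gave 0.204 for intergenic minus ORF, 0.278 for chromosome ends and 269 features below. Normexp gave 1.18, 0.961 and an odds ratio of 1.28 for divergent against tandem gaps. Loess gave an odds ratio of 1.22, 120 below and 12 lists, with 450 above, or 78.9% of calls. Intergenic and ORF features centred apart gave 1.19, 0.325 for chromosome ends and 245 below, and no intergenic minus ORF difference, which is 0 by construction. Centring on the shared features gave 248 below. eBayes with a trend gave 0 below (499 at an unadjusted p under 0.05), and duplicateCorrelation 222 below. An estimated correlation gave 0 lists in camera, against 7, with unadjusted camera p from 0.038 to 0.326 for these 7. Chromosome ends gave 0.161 at 50 kb, 0.413 at 200 kb, 0.269 for intergenic and 0.437 for ORF features alone. Print batch F060D alone gave 0.412 for intergenic minus ORF.

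Leaving out each replicate in turn gave a mean r of 0.413 to 0.735, 228 to 477 features above, 30 to 696 below and 5 to 11 lists. The divergent against tandem odds ratio ranged from 0.988 without replicate 3 to 1.24. All 7 called lists lost their call in camera with an estimated correlation and with replicate 3 read with the same letters. Upstream features of glycolysis and iron uptake genes were called in the other 13 of 15 settings. With undetected input set to a low signal the hexose transporter, glucose-repressed and stress response lists and both ORF lists also lost it. Without replicate 3 the stress response list (camera adjusted p = 0.138) and the glucose-repressed ORF list (0.0684) did, and without dim input spots the glucose-repressed upstream list. Their mean differences were then 0.41, 0.55 and 0.52, against 0.58, 0.53 and 0.71 in the main fit.

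Camera was not run for features on at least 2 arrays, because of missing values. The comparison with convergent gaps was not run, because placing features 5' of their genes leaves none in such a gap. No paired analysis was possible because the 3 arrays form a single group. Undetected input limits how many features could be used: 3635 and 6935 spots on replicates 1 and 2 had a precipitate signal and no input signal, while 83 and 51 had the reverse. The input's median signal over local background was 6.40, 6.02 and 14.3 on replicates 1 to 3.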

Other observations

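Of 1819 genes with a measured upstream feature, 508 (27.9%) had one on the binding list. Among 76 words that describe the products of at least 8 of these genes, only "glucose" passed: all 9 of its genes had a listed upstream feature (Fisher's exact test, adjusted p = 0.000746). They were the transporter genes ght2, ght5 and ght6, the repressor gene scr1, the glucose-6-phosphate dehydrogenase genes zwf1 and gcd1, and fyu1, gal10 and uge1 of sugar nucleotide metabolism. The word "transporter" had 34 of 86 genes (adjusted p = 0.285), among them tna1, zrt1, fio1 and str1, and "meiotic" 6 of 8 (adjusted p = 0.231), of which wtf4, wtf5, wtf13 and wtf18 belong to a family of near-identical sequences. With replicate 3 read with the same letters 5 of the 9 glucose genes were listed (adjusted p = 0.469), and by Fisher's exact test 0 words passed, with 5 at an unadjusted p under 0.05. The result for glucose thus rests on the direction taken for that array, and its loss under the turned sign follows in part by construction. The words were tested after the lists had been seen.

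Listed features also lay together along chromosome I. Of 613 windows of 20 kb, 5 held 5 listed features, against a mean of 0.4 and at most 4 windows in 1000 shuffles of the features (permutation p = 0.001, the smallest they can give), where the shuffles move each feature alone although neighbours share gaps. The fullest window held 5 listed features, and shuffles reached 7 in a window. In the same-letters reading 2 windows held at least 5, against a mean of 0.06 and at most 2 in the shuffles (permutation p = 0.003). The windows starting at 60001 (dak2, ght3), 100001 (pdc101), 1140001 (SPAC56F8.13), 1820001 (psu1, tna1) and 4220001 (fio1, fip1) were these. Among centromeric repeats, whose copies are near-identical and uncertain, the dg1 feature had -1.17 ± 0.52 and the partial dhII feature -1.28 ± 0.94, and both passed in limma. The dgII feature (-0.58 ± 0.65), the feature between dhII and dgII (-0.70 ± 0.84) and the dh1 feature (0.64 ± 0.12) did not. In the same-letters reading these 5 had -0.76, -0.96, -0.65, -0.73 and 0.27, and none passed. Both windows and repeats, and the same-letters reading throughout, were chosen after seeing the data.

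Of the tests below, those of dim input and of GC content and length on the gene lists were set before their results were seen, and all others after. Intergenic features lay above ORF features on every array. In a regression with GC content and length the coefficient of feature kind was 0.89 ± 0.14 (n = 3 arrays, 0.79 ± 0.18 without them), which argues against these as the whole cause. A lowess on GC content and length, which differ between the kinds, left 0.204, so how the difference divides between kind and composition stays open. After loess the difference was 0.54 ± 0.15 and without dim input spots 0.53 ± 0.19, against 0.71 ± 0.27, which argues against signal intensity as the whole cause. These statements hold for the likely direction of replicate 3 and for that alone: with the same letters the coefficient was 0.29 ± 1.03, and the differences 0.26 ± 0.59 after loess and 0.30 ± 0.57 without dim input spots. The values on hand favour the likely direction: under it the mitochondrial features had medians of -3.10, -3.77 and -2.12, all low, and the other reading would turn the sign on replicate 3 alone. The labels do not state it. No biological explanation was tested, since there is a single group and no untagged strain.

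The upstream features of the 5 called intergenic lists had a pooled median 1.04 above all intergenic features. If strongly transcribed chromatin were recovered more, ribosomal protein genes would share the shift. Their 75 measured upstream features, of 176 on the array, lay at -0.03 from the median of all intergenic features. For the features measured, this argues against a gain at all strongly transcribed genes. Recovery stays open as a cause of the pattern, since other genes of strong transcription were raised: the glycolysis list, the ef1-b feature (2.94), the gap of tef103 (2.81) and 4 of 5 features upstream of histone genes (median 0.92 against 0.39), which lie in 2 divergent gaps. Neither list passed in camera (adjusted p = 0.408 for histone and 0.68 for translation factor genes), and of 5 translation factor features 2 were above, with a shift of 0.31. Without dim input spots 4 of the 5 lists kept their call, with a pooled shift of 0.51 over 38 in place of 77 members, and glucose-repressed genes lost it. By list, the mean difference from all intergenic features was then 1.19 for glycolysis (1.23 with dim spots) and 1.24 for hexose transporter genes (0.87). It was 1.22 for iron uptake (1.12), 0.69 for stress response (0.58) and 0.52 for glucose-repressed genes (0.71). After removal of GC content and length 5 of 5 lists kept their call. Read with the same letters, the pooled shift was 0.10 and no list was called. Turning the sign of a correlated array shrinks a shared shift by construction, so this loss does not test the pattern. It shows that the calls rest on the direction taken for replicate 3. Correlation between features stays open, since no list passed with an estimated one, and no biological explanation was tested. That estimate rests on 3 arrays, so it can decide little. The unadjusted camera p with it was 0.065 for iron uptake, 0.093 for hexose transporter and 0.126 for glycolysis upstream features. It was 0.144 for glucose-repressed and 0.326 for stress response ones. For ORF features it was 0.038 for iron uptake and 0.18 for glucose-repressed genes.

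The 67 listed ORF features may in part owe their signal to fragments that reach in from a raised neighbouring region. This was tested on 1115 of the 2692 measured ORF features, which did not include all of the 67. Of 345 ORF features touching a listed intergenic feature 35 (10.1%) were listed, and of the 770 others in the test 8 (1.0%) (Fisher's exact test, odds ratio 10.75, p = 4.46e-12). The coding sequences of the 60 listed ORF features with coordinates differed by -598 bp in median from the others (742.5 against 1341 bp, permutation p = 4e-05). The same-letters reading gave an odds ratio of 2.33 (Fisher's exact test, p = 0.019) and a length difference of -459 bp (permutation p = 0.0003). This is a hypothesis, as the pattern was found and tested on the same data. Binding within short genes could also give the length difference and was not tested.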
